A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

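The data were 15 RNA libraries of the budding yeast Saccharomyces cerevisiae strain BY4741, with 3 in each of 5 groups. Per the labels, cells grew in a yeast nitrogen base medium with β-glycerophosphate, a phosphate ester, and were exposed for 1 h to lanthanum (La, a light rare earth element) at 50 or 160 µM or to ytterbium (Yb, a heavy one) at 6 or 8 µM, or were left untreated. The series description speaks of retinal profiles of yeast, while the label of every sample gives yeast cells, and the labels were followed. The labels give the lower dose of each metal as its EC10 and the higher as its EC50, the doses with 10 and 50 percent effect. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

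The deposited table held, for 6600 gene identifiers, the signal of each library, which the authors had made by dividing gene counts by 1 size factor per library, together with 5 columns of group means. Strand-specific TruSeq libraries were prepared, per the labels. FastQC 0.67, TopHat2 2.1.1, HTSeq 0.6.1p1, DESeq2 1.14.1 and the genome build R64 are named in the submitters' processing notes, and their roles, their order and the strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain, as are near-identical copies such as ENA1 and its neighbours, PHO11 and PHO12, HXT6 and HXT7, SSA1 and SSA2, and the duplicated histone and ribosomal protein genes. The deposited values of each library were whole multiples of the worth of 1 read (0.901 to 1.22 normalized counts), and 100% of them came out whole within a tolerance of 0.01. The recovered totals ranged from 5629666 to 7183175 reads per library. A library with 0 reads of a gene allows up to 3 reads, between 2.70 and 3.67 normalized counts, and such limits cover counting error only. The authors' deposited mean columns matched the means of the 3 libraries and were not used further. Column names gave each library's group and a running number from 1 to 15 but not the replicate number of the labels, so libraries are named by group and running number.

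Identifiers were matched to the RefSeq annotation of build R64, and 5917 of 6600 matched. Coordinates are from that annotation and 1-based. Its gene lengths were all multiples of 3 and are called coding length. Genes with a mean of at least 10 normalized counts over the 15 libraries were tested (5567 genes, 98.6% of them with a coding length); 146 genes had no read in any library. Values were transformed to log2(normalized count + 1), so every log2 change is on that scale, which understates the change of low genes. Replicates were compared within groups before averaging: a chi-square of their reads divided by its degrees of freedom was between 2.97 and 28.0 for every pair, above sampling noise, so none was treated as a duplicate. Pearson's r of the log2 values of such pairs, across genes, was 0.987 to 0.995.

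Tests were 2-sided contrasts in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a mean-variance trend, in a single fit to all 15 libraries with 1 coefficient per group. Adjusted p-values are Benjamini-Hochberg values from limma over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were each dose of each metal with control, the doses of each metal with each other, the metals with each other at each effect level, the difference between the dose steps of the metals, the metals averaged over both levels, and an F test over all groups. An exact permutation test of 3 libraries against 3 cannot give a p below 0.10, so no single gene was tested in that way. Group means are given ± SD with n = 3 libraries and log2 changes ± SE of the fit.

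The tests, 30 gene lists, 4 marker sets, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule took, among genes called with at least a 2-fold change, a mean of at least 50 normalized counts in the higher group and ranges of the 2 groups that did not overlap, the 10 largest rises and 10 largest falls for each metal at EC50 against control and for La EC50 against Yb EC50, and 5 and 5 for the other comparisons. Of each list described, it took up to 4 called members with the largest change, or the 2 with the highest mean where none was called, and it took every marker gene. The result of 1 gene that the rule named is not reported here. The difference between dose steps has no pair of groups, so the range criterion was left out there. The lists were targets of the phosphate starvation, cell wall integrity, calcineurin, osmotic, general stress, heat shock, oxidative stress, iron, zinc, copper, Gcn4, Ino2/Ino4, unfolded protein, Rpn4, Rim101 with ESCRT, Pdr1/Pdr3, pheromone and nitrogen systems, and genes of ribosome biogenesis, ribosomal proteins, sulfur amino acid, ergosterol and fatty acid with sphingolipid metabolism, the respiratory chain, the citrate and glyoxylate cycles, glycolysis, hexose transport, the vacuolar H+-ATPase, histones and the cell cycle. They share members: HSP12, CTT1, ALD3 and TFS1 are in both the osmotic and the general stress list, and HSP26, HSP42, HSP78, HSP104 and SSA4 are in both the general stress and the heat shock list. The calcineurin list shares GSC2 with the cell wall integrity list and PHO89 with the phosphate starvation list. The Pdr1/Pdr3 list shares GRE2 with the osmotic list, and RSB1 and IPT1 with the fatty acid and sphingolipid list. Of 671 list symbols, AAD6, AAD16 and CRS5 had no match. Lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, and again with an estimated correlation. Counts of called members are given over all genes tested and adjusted over the list alone.

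The script of the fit was tested on simulated counts drawn from the means, dispersions and depths of the real libraries, with 200 of 5567 genes changed. Each gene was drawn independently, so variation shared by many genes was left out. In the real libraries 1 component held 21.9% of the variance within groups. The calls of unchanged genes given here may therefore understate the error in these data. For La EC10 against control, 89.6% of 67 genes changed 1.5-fold were called in their direction, 97.0% of 67 changed 2-fold and 100.0% of 66 changed 4-fold, with 9 calls of unchanged genes. For La EC50 against control the shares were 82.1%, 92.5% and 100.0%, with 10 such calls. For Yb EC10 against control the shares were 88.1%, 97.0% and 98.5%, with 14 such calls. For Yb EC50 against control the shares were 92.5%, 97.0% and 98.5%, with 8 such calls. For La EC50 against La EC10 the shares were 85.1%, 94.0% and 100.0%, with 13 such calls. For Yb EC50 against Yb EC10 the shares were 88.1%, 98.5% and 100.0%, with 7 such calls. For La EC10 against Yb EC10 the shares were 88.1%, 97.0% and 100.0%, with 16 such calls. For La EC50 against Yb EC50 the shares were 89.6%, 98.5% and 100.0%, with 11 such calls.

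Alternatives were a pseudocount of 0.5 or 5, no filter or a mean of at least 50, values rescaled to an equal total per library, quantile normalization, limma without a trend and with robust moderation, a fit to only the 6 libraries compared, and leaving out each library in turn. Further alternatives were chosen after seeing the data: edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, removal of each library's smooth trend with coding length or GC content, and removal of a component of the differences between libraries of a group. Of the first 2 components, the one that went more with coding length was taken, called the short-gene component. Removing it also takes out differences between groups along it. A call lost in that fit therefore cannot tell variation between libraries from an effect of the metals. The edgeR and DESeq2 tests called 1437 and 1331 genes for La EC50 against control, where limma called 1425, and 2306 and 2108 for Yb EC50 against control, where limma called 2274. The overlap of calls between comparisons that share controls was set beside 100 simulations of unchanged groups and beside the overlap of independent lists. For each count of genes, other splits of the same libraries were fitted, all 10 for 3 libraries against 3 and 100 drawn for the others.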

Results

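The series compared the transcriptome of yeast after exposure to a light and a heavy rare earth element, La and Yb. It held 3 libraries each of untreated cells, cells exposed for 1 h to La at 50 µM (EC10) or 160 µM (EC50), and cells exposed to Yb at 6 µM (EC10) or 8 µM (EC50). Depth was similar: the recovered totals were 5629666 to 6478993 reads in the control libraries, 6088849 to 7079746 at La EC10, 6220111 to 7183175 at La EC50, 6122514 to 6497308 at Yb EC10 and 6372092 to 6895514 at Yb EC50. Of 5567 genes tested, 2402 differed among the 5 groups (limma F test). On the leading principal component, with 46.0% of the variance, control libraries lay between -18.1 and -14.1, La libraries between -9.28 and -3.73, and Yb libraries between 2.09 and 24.7.

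The marker genes fitted a haploid strain of mating type a. URA3 and MET17, deleted in BY4741, had 0 reads in all 15 libraries and LEU2, also deleted, had 1 read in Yb EC10 library 7 and 0 elsewhere. HIS3 stayed at 382 to 488 normalized counts per group, and since its deletion in this strain is partial it checks nothing. The α-factor gene MF(ALPHA)1 stayed at or below 11.7 normalized counts in every library, MF(ALPHA)2 had group means of 0 to 2.87 and the α-type receptor gene STE3 had 50.3 to 71.5. The a-type genes were abundant in control cells, with 5021 ± 812 normalized counts for the a-factor gene MFA2 and 5775 ± 308 for the α-factor receptor gene STE2 (SD, n = 3).

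All 7 a-type markers were lower after La. BAR1, the protease that degrades α-factor, had 2730.3 ± 153 normalized counts in control, 1151 ± 95.5 at La EC10 and 1282 ± 9.70 at La EC50, against 2141 ± 158 and 2000.2 ± 152 at Yb EC10 and Yb EC50 (SD, n = 3). At La EC50 the log2 changes from control were -1.43 ± 0.13 for MFA1, -1.09 ± 0.08 for BAR1, -1.07 ± 0.08 for the agglutinin subunit gene AGA2, -0.77 ± 0.15 for ASG7, -0.71 ± 0.11 for MFA2, -0.61 ± 0.07 for STE2 and -0.41 ± 0.07 for the a-factor exporter gene STE6 (SE; adjusted p between 5.08e-08 and 0.00166). The corresponding changes at Yb EC50 ran from -0.99 for MFA1 to -0.40 for ASG7. SAG1, the α-agglutinin gene, rose from 234 ± 21.0 to 300.1 ± 16.0 at La EC50 (adjusted p = 0.00283), and to 269 ± 10.5 at Yb EC50 (adjusted p = 0.0422). Among meiotic genes the kinase gene IME2 rose with each metal, from 72.1 ± 8.34 to 168 ± 4.31 and 184 ± 8.92 with La and to 126 ± 15.9 and 146 ± 10.9 with Yb, and SPO11 rose from 38.1 ± 6.96 to 54.5 ± 3.32 and 65.6 ± 6.49 with La and to 58.0 ± 0.921 and 62.0 ± 9.49 with Yb (adjusted p between 0.00155 and 0.0252). Group means of the other meiotic markers were 28.5 to 49.2 for HOP1, 35.2 to 52.7 for DMC1, 235 to 277 for ZIP1, 89.9 to 123 for SPS4, 55.0 to 69.7 for DIT1, 42.8 to 54.3 for NDT80, 29.99 to 42.8 for SPS1, 8.83 to 21.3 for DIT2, 7.77 to 12.2 for SPR3, 4.96 to 8.11 for SPO13 and 0 to 3.51 for SPS2. HOP1 was at 24.5 to 30.9 in control and higher in every exposed library. Its lowest values were 43.5 and 35.1 at La EC10 and La EC50, and 44.0 and 41.9 at Yb EC10 and Yb EC50. DIT2 was at 18.0 to 23.9 at La EC50, against 3.19 to 12.4 in control. Of these other markers only HOP1 lay above its control range in every exposed group.

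At La EC50 KDX1 (YKL161C, chromosome XI, 149386 to 150687, 1 coding exon), a kinase gene of the cell wall integrity pathway, went from 131 ± 17.2 to 1233 ± 15.2 normalized counts (SD, n = 3), a log2 change of 3.24 ± 0.11 (SE, adjusted p = 1.53e-11). INO1 (YJL153C, chromosome X, 134332 to 135933, 1 coding exon), which makes inositol phosphate for phosphatidylinositol, went from 122 ± 7.92 to 750.0 ± 38.1, 6.11-fold. The other rises named by the rule were the methyltransferase gene CRG1 (log2 change 2.53 ± 0.09), SRL3 (2.52 ± 0.09), the oligopeptide transporter gene OPT2 (2.44 ± 0.27), the cell wall mannoprotein genes CWP1 (2.39 ± 0.10) and PIR3 (2.22 ± 0.19), YPL088W (2.05 ± 0.08), YCL049C (2.03 ± 0.13) and the hexose transporter gene HXT4 (1.95 ± 0.15). The largest fall was CHA1 (YCL064C, chromosome III, 15798 to 16880, 1 coding exon), the catabolic serine and threonine deaminase gene, from 425 ± 18.2 to 107 ± 8.98 (adjusted p = 1e-07). The other falls named were the purine synthesis gene ADE17 (-1.78 ± 0.07), the serine hydroxymethyltransferase gene SHM2 (-1.66 ± 0.06), the glycine decarboxylase subunit gene GCV2 (-1.43 ± 0.08), RRT5 (-1.74 ± 0.33), the mating genes PRM1 (-1.68 ± 0.23), MFA1 (-1.43 ± 0.13) and FAR1 (-1.31 ± 0.10), the phosphate-regulated gene PHM6 (-1.42 ± 0.19) and the malic enzyme gene MAE1 (-1.32 ± 0.12).

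Of the cell wall integrity list, targets of the kinase Slt2 and the factor Rlm1, 22 of 23 rose and 0 fell, or 22 and 1 adjusted over the list alone at La EC50, with a median log2 change of 1.06 (camera, adjusted p = 1.41e-24 and adjusted p = 0.00142 with an estimated correlation). PRM5 of that list changed by 1.84 ± 0.08. Of the ribosomal protein genes 1 of 138 rose and 110 fell, or 1 and 116 adjusted over the list alone (median -0.39, adjusted p = 1.94e-26 and adjusted p = 0.305 with an estimated correlation). Their median was -0.29 with equal totals and -0.17 with quantile normalization, so the size of the fall depended on the scaling. The list stayed called in both at the preset correlation. RPL7B changed by -1.004 ± 0.07 and RPL8A by -0.93 ± 0.10. Of the ribosome biogenesis genes 0 of 70 rose and 47 fell, or 0 and 61 adjusted over the list alone (median -0.37, adjusted p = 7.35e-17 and adjusted p = 0.463 with an estimated correlation). NOG1 changed by -0.67 ± 0.12 and PWP2 by -0.62 ± 0.11. Of the pheromone response genes 1 of 14 rose and 11 fell, or 1 and 11 adjusted over the list alone (adjusted p = 7.97e-07 and adjusted p = 0.0312 with an estimated correlation). FIG1 changed by -1.55 ± 0.38 and AGA1 by -1.26 ± 0.11. Of the Ino2/Ino4 phospholipid genes 10 of 17 rose and 0 fell, or 12 and 1 adjusted over the list alone (adjusted p = 6.34e-06 and adjusted p = 0.0321 with an estimated correlation). The phospholipid methyltransferase gene OPI3 changed by 0.89 ± 0.08, the inositol transporter gene ITR1 by 0.79 ± 0.09 and the phosphatidylserine synthase gene CHO1 by 0.69 ± 0.09. The Ino2/Ino4 list was also called higher at La EC10, Yb EC10 and Yb EC50. With equal totals its camera adjusted p there was 0.000295, 0.00178 and 0.00669. The calls at those exposures did not hold with an estimated correlation. Of the phosphate starvation genes 2 of 17 rose and 11 fell, or 2 and 12 adjusted over the list alone (adjusted p = 6.34e-06 and adjusted p = 0.185 with an estimated correlation). The phosphate transporter gene PHO84 changed by -0.89 ± 0.09. Of the heat shock genes 1 of 23 rose and 13 fell, or 1 and 15 adjusted over the list alone (adjusted p = 0.000101 and adjusted p = 0.185 with an estimated correlation). HSP26 changed by -1.29 ± 0.35 and SSA4 by -0.50 ± 0.13. Of the 31 general stress genes 3 rose and 3 fell at La EC50, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.408 and adjusted p = 0.904 with an estimated correlation).

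In all, 1425 genes were called for La EC50 against control, 703 higher and 722 lower, of which 74 and 28 changed at least 2-fold. Rescaling every library to an equal total moved the median of all genes from 0.01 to 0.11 and gave 1195 higher and 416 lower calls, 74.2% higher in place of 49.3%, and the falls above are relative to the median gene.

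**Figure D1:**
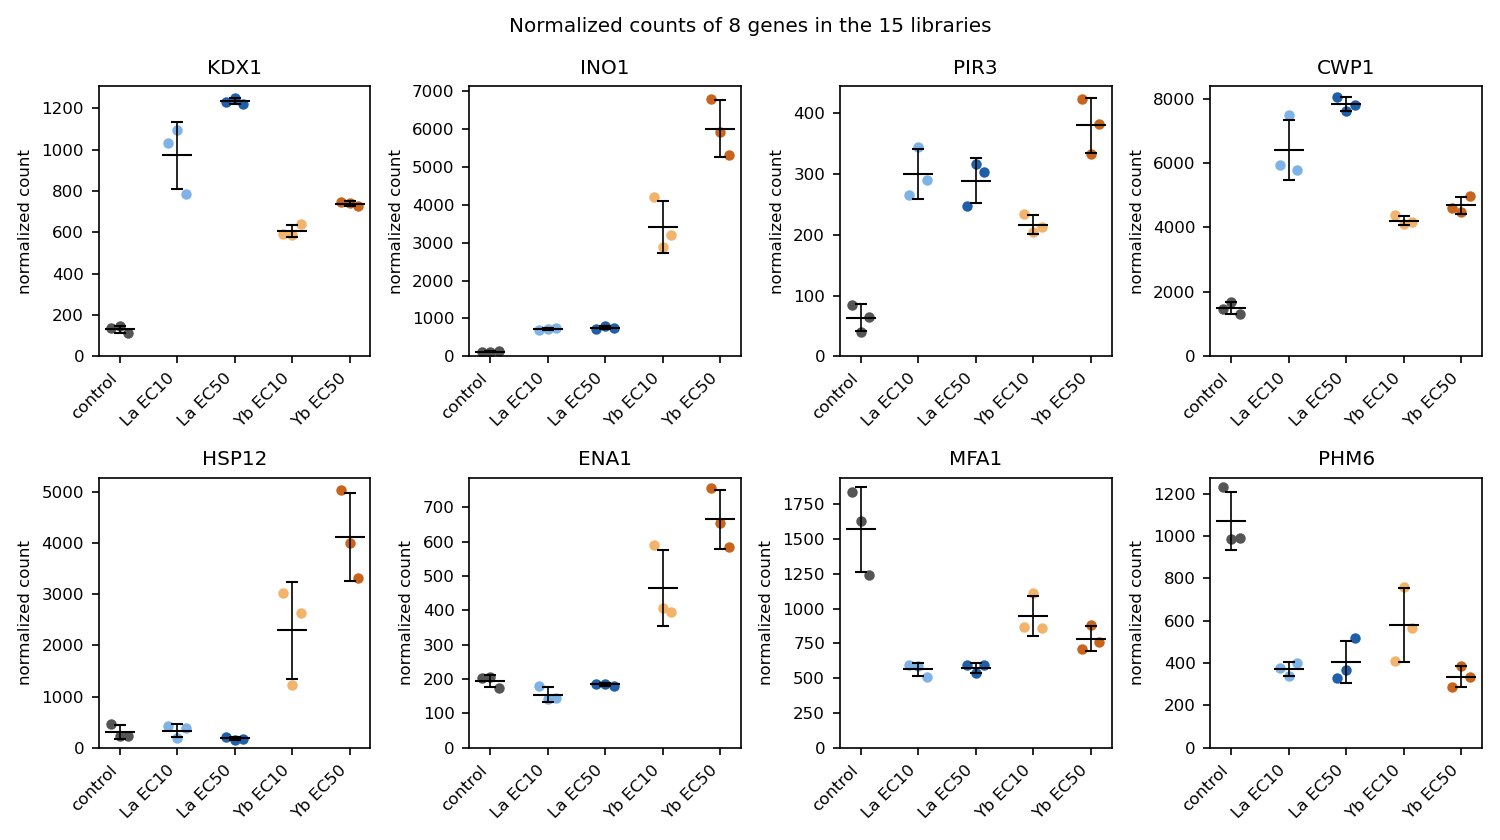
Normalized counts of 8 genes in each of the 15 libraries. Points are libraries, bars the mean and SD of 3 libraries per group. KDX1 was above its control range in all 12 exposed libraries, while HSP12 and ENA1 were above theirs in the 6 Yb libraries only.

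La at EC10 changed many of the same genes. KDX1 rose to 971 ± 163 normalized counts, a log2 change of 2.88 ± 0.11 (SE, n = 3, adjusted p = 1.16e-10), and INO1 rose to 724 ± 21.8. PIR3 (2.28 ± 0.19), CRG1 (2.22 ± 0.09) and CWP1 (2.09 ± 0.10) were the other rises named, and SED1, a cell wall glycoprotein gene, rose by 1.48 ± 0.10. The falls named were PRM1 (-2.12 ± 0.23), CHA1 (-2.01 ± 0.15), the sodium-phosphate transporter gene PHO89 (-1.69 ± 0.09), PHM6 (-1.52 ± 0.19) and the acid phosphatase gene PHO12 (-1.47 ± 0.13). Its near-identical copy PHO11 changed by -1.39 ± 0.16.

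Of the cell wall integrity genes 20 of 23 rose and 1 fell, or 20 and 1 adjusted over the list alone at La EC10 (median 0.93, adjusted p = 2.61e-22 and adjusted p = 0.00203 with an estimated correlation). Of the pheromone response genes 1 of 14 rose and 11 fell, or 1 and 11 adjusted over the list alone (median -0.73, adjusted p = 9.18e-10 and adjusted p = 0.00849 with an estimated correlation). The fusion gene FUS1 changed by -1.37 ± 0.12, AGA1 by -1.28 ± 0.11 and FAR1 by -1.13 ± 0.10. Of the phosphate starvation genes 2 of 17 rose and 14 fell, or 2 and 14 adjusted over the list alone (median -0.64, adjusted p = 1.24e-11 and adjusted p = 0.0525 with an estimated correlation). Of the ribosomal protein genes 0 of 138 rose and 70 fell, or 0 and 110 adjusted over the list alone (adjusted p = 9.94e-21 and adjusted p = 0.42 with an estimated correlation). RPS25B changed by -0.44 ± 0.10. Of the ribosome biogenesis genes 0 of 70 rose and 48 fell, or 0 and 66 adjusted over the list alone (adjusted p = 3.19e-18 and adjusted p = 0.42 with an estimated correlation). LTV1 changed by -0.57 ± 0.12. Of the general stress genes 10 of 31 rose and 0 fell, or 10 and 0 adjusted over the list alone (adjusted p = 3.98e-06 and adjusted p = 0.605 with an estimated correlation). The hexokinase gene HXK1 changed by 1.16 ± 0.22 and the glycogen synthase gene GSY1 by 1.07 ± 0.23. The mean deviation of the stress list was -0.528 in La EC10 library 14, within the control range of -0.861 to -0.524, and -0.167 and -0.104 in libraries 13 and 15. Of the unfolded protein response genes 11 of 16 rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 3.98e-06 and adjusted p = 0.42 with an estimated correlation). The chaperone gene KAR2 changed by 0.58 ± 0.12 and the oxidase gene ERO1 by 0.64 ± 0.11. That list's mean deviation was -0.0676 in La EC10 library 14 and 0.264 and 0.293 in libraries 13 and 15, against -0.262 to -0.125 in control. The unfolded protein list was also called higher at Yb EC10 (camera adjusted p = 0.00354 with equal totals). Its call at La EC50 ended with equal totals (camera adjusted p = 0.0646). Of the respiratory chain genes 19 of 36 rose and 0 fell, or 24 and 0 adjusted over the list alone (adjusted p = 4.7e-09 and adjusted p = 0.0525 with an estimated correlation). SDH1 changed by 0.57 ± 0.08. The respiratory chain list was also called higher at La EC50, Yb EC10 and Yb EC50. With equal totals its camera adjusted p there was 2.68e-05, 1.26e-06 and 0.00109. Those calls did not hold with an estimated correlation.

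In all, 1131 genes were called for La EC10 against control, 569 higher and 562 lower, 50 and 22 of them at least 2-fold, and with equal totals the calls were 767 higher and 311 lower (71.2% higher against 50.3%). The count fell to 639 without control library 2, 707 without control library 3, 618 without La EC10 library 13 and 577 without La EC10 library 15.

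Yb at EC50 raised general stress genes by far more than La did, beside the cell wall genes. INO1 went from 122 ± 7.92 to 6011 ± 752 normalized counts (SD, n = 3), 48.7-fold, a log2 change of 5.61 ± 0.11 (adjusted p = 1.08e-14). HSP12 (YFL014W, chromosome VI, 107256 to 107585, 1 coding exon), a small membrane-protecting heat shock protein gene, went from 310.3 ± 138 to 4114 ± 866. The other rises named were CPP3 (log2 change 5.36 ± 0.28), the energy metabolism gene RGI2 (4.78 ± 0.56), TMA10 (4.33 ± 0.27), RTC3 (3.84 ± 0.20), the endosomal GTPase gene YPT53 (3.83 ± 0.33), the hexose transporter gene HXT5 (3.55 ± 0.38) and the transaldolase gene NQM1 (3.28 ± 0.27). The falls named were smaller: YBR012C (-1.69 ± 0.21, without coordinates in the annotation used), PHM6 (-1.67 ± 0.19), EFG1 (-1.57 ± 0.34), CSN9 (-1.53 ± 0.39), CGR1 (-1.21 ± 0.28), ZEO1 (-1.17 ± 0.32), YBL028C (-1.141 ± 0.23), RRT5 (-1.13 ± 0.33), EXP1 (-1.12 ± 0.23) and PRM1 (-1.10 ± 0.23). The calls of CSN9, ZEO1 and CGR1 ended when a component that varied within groups was removed (adjusted p = 0.261, 0.475 and 0.0859; ranges 0.00032 to 0.261, 0.00095 to 0.475 and 0.000125 to 0.0859). That removal also takes out differences from control along the component, so it does not show the cause of these falls. The 26 genes at least 2-fold lower had a median coding length of 468 bases where one was known, against 1245 over all genes tested.

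Of the general stress genes, targets of Msn2 and Msn4, 29 of 31 rose and 0 fell, or 30 and 0 adjusted over the list alone at Yb EC50 (median 1.84, adjusted p = 8.27e-20 and adjusted p = 0.188 with an estimated correlation). The repressor gene XBP1 changed by 3.10 ± 0.26 and HXK1 by 2.94 ± 0.22. Of the osmotic stress genes 12 of 14 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 1.33, adjusted p = 1.3e-06 and adjusted p = 0.169 with an estimated correlation). The catalase gene CTT1 changed by 1.59 ± 0.20, ALD3 by 1.82 ± 0.20 and TFS1 by 2.02 ± 0.23. Of the calcineurin targets 10 of 14 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 0.73, adjusted p = 1.26e-06 and adjusted p = 0.169 with an estimated correlation). The sodium pump gene ENA1 changed by 1.76 ± 0.14, the glucan synthase gene GSC2 by 1.71 ± 0.09 and the kinase gene CMK2 by 1.60 ± 0.09. Of the cell wall integrity genes 22 of 23 rose and 0 fell, or 22 and 0 adjusted over the list alone (median 1.19, adjusted p = 3.09e-19 and adjusted p = 0.00415 with an estimated correlation). PIR3 changed by 2.62 ± 0.19, KDX1 by 2.50 ± 0.11 and NCW2 by 2.35 ± 0.08. Of the ribosomal protein genes 0 of 138 rose and 134 fell, or 1 and 136 adjusted over the list alone (median -0.41, adjusted p = 6.61e-24 and adjusted p = 0.228 with an estimated correlation). With equal totals their median was -0.27 and with quantile normalization -0.17, so here too the size of the fall depended on the scaling. RPL29 changed by -1.08 ± 0.27. Of the ribosome biogenesis genes 0 of 70 rose and 60 fell, or 0 and 66 adjusted over the list alone (adjusted p = 4.29e-13 and adjusted p = 0.384 with an estimated correlation). RRP1 changed by -0.57 ± 0.09. Of the phosphate starvation genes 1 of 17 rose and 12 fell, or 1 and 13 adjusted over the list alone (adjusted p = 3.16e-06 and adjusted p = 0.169 with an estimated correlation). SPL2 changed by -1.05 ± 0.12 and PHO84 by -0.85 ± 0.09. Of the Pdr1/Pdr3 targets 9 of 13 rose and 0 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.000116 and adjusted p = 0.169 with an estimated correlation). RTA1 changed by 3.12 ± 0.32.

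In all, 2274 genes were called for Yb EC50 against control, 1148 higher and 1126 lower, 243 and 26 of them at least 2-fold. With equal totals, which moved the median of all genes from -0.02 to 0.11, the calls were 1755 higher and 472 lower (78.8% higher against 50.5%), and without Yb EC50 library 4 the count was 1515. The call of RRT5 ended without control library 2 (adjusted p = 0.0555) and without Yb EC50 library 4 (0.0547), over a range of 0.00211 to 0.0555 across its alternatives.

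**Figure D2:**
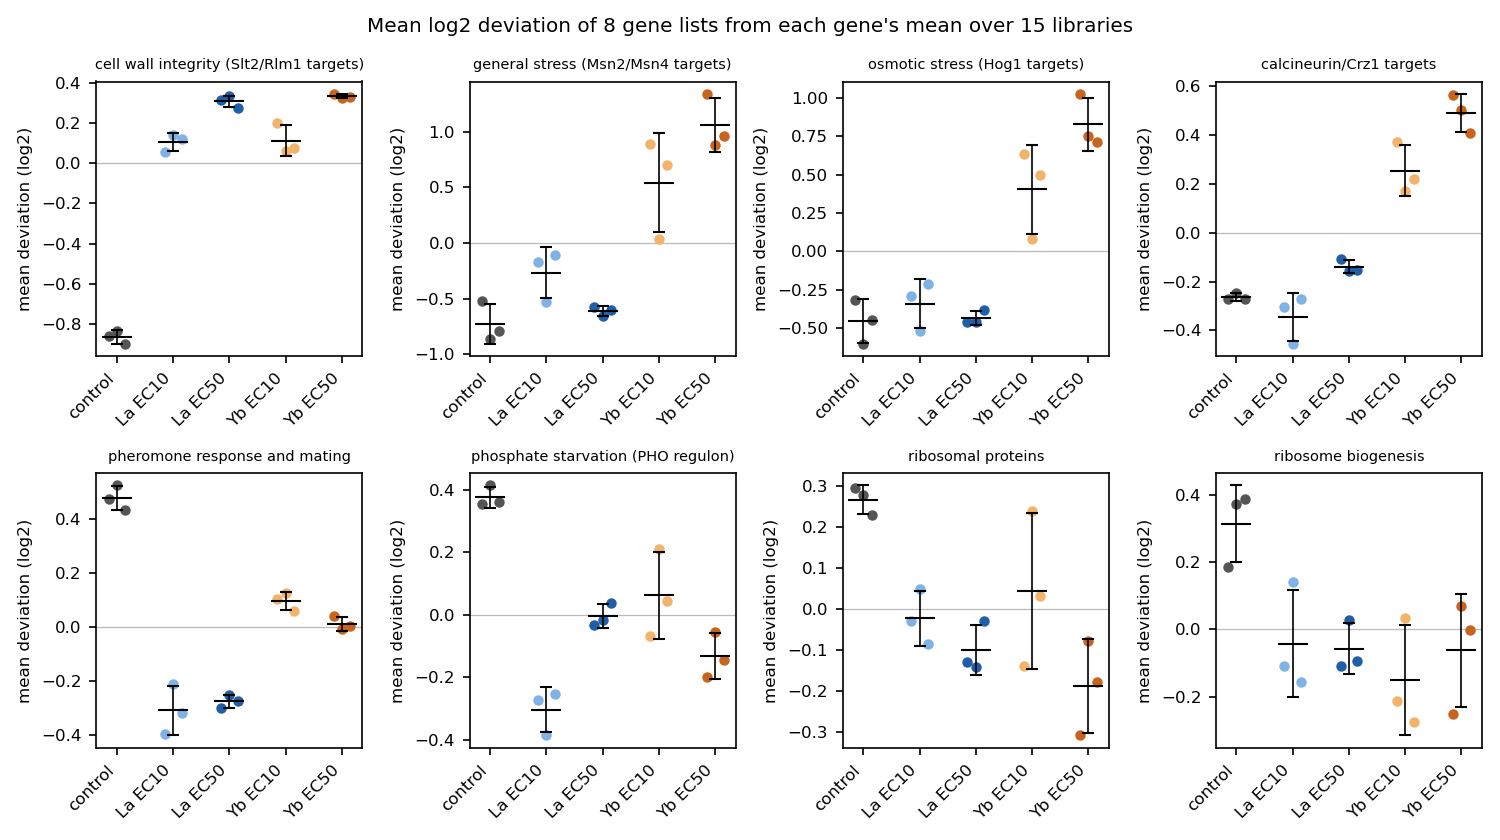
Mean deviation (log2) of the tested members of 8 gene lists from each gene's mean over the 15 libraries. Points are libraries, bars the mean and SD of 3 libraries per group. The cell wall list was above control in all 12 exposed libraries, and the general stress list was above all 9 control and La libraries in the 6 Yb libraries, by least in Yb EC10 library 8.

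Yb at EC10 gave the same leading genes. INO1 rose to 3425 ± 688 normalized counts (SD, n = 3; log2 change 4.78 ± 0.11, adjusted p = 1.24e-13), and CPP3 (4.46 ± 0.28), RGI2 (4.18 ± 0.56) and TMA10 (4.04 ± 0.27) were the other rises named. No fall met every criterion of the rule, and the 1 gene at least 2-fold lower, chosen here after its values were seen, was the mitochondrial fatty acid synthesis gene OAR1, from 40.7 ± 6.48 to 18.9 ± 1.63 (adjusted p = 0.00279).

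Of the general stress genes 28 of 31 rose and 0 fell, or 29 and 0 adjusted over the list alone at Yb EC10 (median 1.30, adjusted p = 4.46e-17 and adjusted p = 0.236 with an estimated correlation). HSP12 changed by 2.87 ± 0.35 and NQM1 by 2.58 ± 0.27. Of the cell wall integrity genes 22 of 23 rose and 0 fell, or 22 and 0 adjusted over the list alone (median 0.94, adjusted p = 2.81e-21 and adjusted p = 0.00262 with an estimated correlation). KDX1 changed by 2.21 ± 0.11. Of the ribosome biogenesis genes 0 of 70 rose and 69 fell, or 0 and 70 adjusted over the list alone (median -0.47, adjusted p = 1.12e-22 and adjusted p = 0.258 with an estimated correlation). DBP2 changed by -0.66 ± 0.17. Of the ribosomal protein genes 0 of 138 rose and 52 fell, or 0 and 68 adjusted over the list alone (adjusted p = 6.76e-13 and adjusted p = 0.467 with an estimated correlation). RPL11B changed by -0.39 ± 0.10. The mean deviation of that list was 0.240 in Yb EC10 library 8, within the control range of 0.229 to 0.295, and -0.140 and 0.0312 in libraries 7 and 9. Of the calcineurin targets 10 of 14 rose and 0 fell, or 10 and 1 adjusted over the list alone (adjusted p = 3.75e-06 and adjusted p = 0.215 with an estimated correlation). ENA1 changed by 1.23 ± 0.14. Of the osmotic stress genes 10 of 14 rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 6.68e-05 and adjusted p = 0.236 with an estimated correlation). HOR7 changed by 1.32 ± 0.12. Of the pheromone response genes 2 of 14 rose and 9 fell, or 2 and 9 adjusted over the list alone (adjusted p = 0.00171 and adjusted p = 0.141 with an estimated correlation). PRM1 changed by -0.80 ± 0.23.

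In all, 1629 genes were called for Yb EC10 against control, 847 higher and 782 lower, 149 and 1 of them at least 2-fold, and with equal totals 1062 higher and 454 lower (70.1% higher against 52.0%). The count was 1067 without control library 2 and 989 without Yb EC10 library 9.

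Between the doses of La, heat shock genes were lower and cell wall genes higher at EC50. HSP26 went from 642 ± 237 normalized counts at EC10 to 168 ± 17.0 at EC50 (SD, n = 3), a log2 change of -1.85 ± 0.35 (adjusted p = 0.0117), the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 changed by -1.65 ± 0.33 and the drug exporter gene AQR1 by -1.004 ± 0.20. The rises named were the pyruvate carrier gene MPC3 (1.497 ± 0.26), PHO11 (1.21 ± 0.16), PHO89 (1.16 ± 0.09), TMA10 (1.137 ± 0.27) and the glucose signalling gene MTH1 (1.06 ± 0.14). The acid phosphatase gene PHO5 had 8051 ± 603 in control, 3576 ± 367 at EC10 and 7232 ± 220.5 at EC50. Of the phosphate starvation genes 4 of 17 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.16, adjusted p = 3.93e-05 and adjusted p = 0.225 with an estimated correlation). Of the heat shock genes 0 of 23 rose and 9 fell, or 0 and 16 adjusted over the list alone (median -0.29, adjusted p = 9.17e-17 and adjusted p = 0.0127 with an estimated correlation). SSA1 changed by -0.66 ± 0.09. Of the cell wall integrity genes 4 of 23 rose and 0 fell, or 13 and 0 adjusted over the list alone (median 0.21, adjusted p = 2.08e-09 and adjusted p = 0.0299 with an estimated correlation). PRM5 changed by 0.47 ± 0.08.

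The doses of La differed in 99 genes, 55 higher and 44 lower at EC50, 6 and 3 of them at least 2-fold, and with equal totals 57 higher and 24 lower (70.4% higher against 55.6%). The count was 44, 58 and 32 without La EC50 library 10, 11 or 12, and 46 and 42 without La EC10 library 13 or 15. The call of HSP26 ended without La EC10 library 13 (0.0718), La EC10 library 15 (0.0698) or La EC50 library 12 (0.0688), that of TDH1 without La EC10 library 13 (0.0867), La EC10 library 15 (0.0783), La EC50 library 10 (0.0663) or La EC50 library 12 (0.0897), that of AQR1 without La EC10 library 15 (0.0698), La EC50 library 10 (0.0801) or La EC50 library 12 (0.0981), that of MPC3 without La EC50 library 12 (0.0543) and that of TMA10 without La EC10 library 13 (0.112), La EC10 library 14 (0.096), La EC10 library 15 (0.0759), La EC50 library 10 (0.142) or La EC50 library 12 (0.174), adjusted p in brackets. Over all their alternatives the adjusted p was 0.000475 to 0.0718 for HSP26, 0.00128 to 0.0897 for TDH1, 0.000403 to 0.0981 for AQR1, 1.38e-05 to 0.0543 for MPC3 and 0.0156 to 0.174 for TMA10.

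Between the doses of Yb few genes differed. CSN9, a COP9 signalosome gene, went from 553 ± 266 normalized counts at EC10 to 145 ± 47.5 at EC50 (SD, n = 3), a log2 change of -1.83 ± 0.39 (adjusted p = 0.0465). The other falls named were YDL085C-A (-1.56 ± 0.33), the RNase P subunit gene POP5 (-1.33 ± 0.29), the kinetochore gene DAD2 (-1.30 ± 0.30) and the prefoldin gene GIM4 (-1.20 ± 0.27). No general stress gene was called between the doses of Yb over all genes tested, with HXK1 at 0.79 ± 0.22 (adjusted p = 0.0669) and PNC1 at 0.48 ± 0.12 (adjusted p = 0.0525). Adjusted over the list alone 18 of 31 were higher at EC50 (median 0.49, adjusted p = 1.18e-12 and adjusted p = 0.335 with an estimated correlation). The list's mean deviation was 0.0385 in Yb EC10 library 8 and 0.702 and 0.887 in libraries 9 and 7, the last above Yb EC50 library 5 at 0.878. In all 61 genes were called, 39 higher and 22 lower, where edgeR called 73 higher and 103 lower and DESeq2 131 and 178, so the balance of rises and falls depended on the tool. The count was 4, 0 and 2 without Yb EC50 library 4, 5 or 6, 536 without Yb EC10 library 7, and 0 and 1 without Yb EC10 library 8 or 9. The call of CSN9 ended without Yb EC10 library 8 (0.218), Yb EC10 library 9 (0.178), Yb EC50 library 4 (0.165), Yb EC50 library 5 (0.0696) or Yb EC50 library 6 (0.114), over a range of 0.00168 to 0.218, adjusted p in brackets. Those of YDL085C-A, POP5, DAD2 and GIM4 ended without the same libraries, with adjusted p up to 0.218. With a component that varied within groups removed, POP5 changed by -0.60 (adjusted p = 0.0783, range 0.00207 to 0.218), DAD2 by -0.54 (0.101, range 0.00294 to 0.218) and GIM4 by -0.57 (0.124, range 0.0051 to 0.218), none of them called. That fit also takes out differences between the doses along the component.

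At EC50 the metals differed in the general stress genes, all 31 of which were lower with La. RGI2 (YIL057C, chromosome IX, 247902 to 248396, 1 coding exon) had 2.51 ± 0.608 normalized counts with La and 134 ± 33.0 with Yb, against 3.97 ± 1.44 in control (SD, n = 3), and HSP12 had 182 ± 29.2 and 4114 ± 866, a log2 difference of -5.26 ± 0.56 for RGI2 and -4.48 ± 0.35 for HSP12 (adjusted p = 4.21e-07). The other genes lower with La were YPT53 (-4.17 ± 0.33), CPP3 (-4.00 ± 0.28), HXT5 (-3.93 ± 0.38), RTA1 (-3.76 ± 0.32), YNL194C (-3.56 ± 0.51), RTC3 (-3.49 ± 0.20) and NQM1 (-3.45 ± 0.27). The genes named as higher with La were CSN9 (2.22 ± 0.39), EFG1 (1.73 ± 0.34), YDL085C-A (1.73 ± 0.33), the cell integrity gene ZEO1 (1.66 ± 0.32), POP5 (1.65 ± 0.29), TMA7 (1.57 ± 0.35), the ubiquitin-like modifier gene URM1 (1.53 ± 0.27), the tropomyosin gene TPM2 (1.53 ± 0.31), EMC6 (1.501 ± 0.33) and CNL1 (1.495 ± 0.31). These were short genes: the 69 genes at least 2-fold higher with La had a median coding length of 366 bases, and ZEO1 also varied within groups, at 15239 in control library 2, 14091 in La EC10 library 14 and 14577 in Yb EC10 library 7 against 24012 to 35492 in the other 9 libraries outside Yb EC50, and 7417 to 11342 in Yb EC50.

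Of the general stress genes 31 of 31 were lower in La EC50 than in Yb EC50, the same count adjusted over the list alone (median -1.56, adjusted p = 1.97e-29 and adjusted p = 0.147 with an estimated correlation). Of the osmotic stress genes 12 of 14 were lower, 13 adjusted over the list alone (adjusted p = 1.89e-11 and adjusted p = 0.0879 with an estimated correlation). HOR7 changed by -1.87 ± 0.12. Of the calcineurin targets 9 of 14 were lower, 9 adjusted over the list alone (adjusted p = 3.1e-07 and adjusted p = 0.147 with an estimated correlation). ENA1 changed by -1.84 ± 0.14, CMK2 by -1.66 ± 0.09 and the calcineurin regulator gene RCN1 by -1.15 ± 0.13. Of the heat shock genes 15 of 23 were lower and 1 higher, 18 and 1 adjusted over the list alone (adjusted p = 3.1e-07 and adjusted p = 0.0879 with an estimated correlation). HSP26 changed by -2.13 ± 0.35 and HSP42 by -1.22 ± 0.16. Of the cell wall integrity genes 6 of 23 were higher and 4 lower with La, 7 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.644 and adjusted p = 0.924 with an estimated correlation). GSC2 changed by -1.38 ± 0.09 and CWP1 by 0.74 ± 0.10. In all 1224 genes were called, 602 higher and 622 lower with La, 69 and 113 at least 2-fold, and 789 without La EC50 library 12. Of the genes named, the calls of TMA7 and EMC6 ended when a component that varied within groups was removed (adjusted p = 0.103, range 8.09e-05 to 0.103, and 0.0648, range 0.000174 to 0.0648). Such a removal takes out differences between the metals along the component too. Of the 69 genes higher with La, 5 stayed called at least 2-fold higher without such a component found in the other 9 libraries, and the median log2 difference went from 1.25 to 0.41.

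At EC10 the direction was the same for the stress genes. RGI2 had 3.44 ± 2.98 normalized counts with La and 91.7 ± 39.1 with Yb (SD, n = 3), a log2 difference of -4.70 ± 0.56 (adjusted p = 5.45e-05), followed by SPG4 (-3.77 ± 0.46), TMA10 (-3.63 ± 0.27), HXT5 (-3.28 ± 0.38) and CPP3 (-3.22 ± 0.28). The 4 genes at least 2-fold higher with La were YOR387C (1.52 ± 0.37), VEL1 (1.42 ± 0.38), the zinc-responsive alcohol dehydrogenase gene ADH4 (1.03 ± 0.27) and the ferric reductase gene FRE4 (1.02 ± 0.28). YOR387C and VEL1 have the same coding length, 621 bases. Their means were close in each group, at 7219 and 7015 at La EC10 and 2019 and 2074 in control. Whether their reads were told apart is not known, so they may not be separate results. The call of YOR387C ended without La EC10 library 13 (0.0859), La EC10 library 15 (0.0904) or Yb EC10 library 8 (0.0602), that of VEL1 without La EC10 library 13 (0.127), La EC10 library 15 (0.122) or Yb EC10 library 8 (0.101), that of ADH4 without La EC10 library 13 (0.105), La EC10 library 15 (0.112) or Yb EC10 library 8 (0.0708) and that of FRE4 without La EC10 library 13 (0.114), La EC10 library 14 (0.0755), La EC10 library 15 (0.102), Yb EC10 library 8 (0.105) or Yb EC10 library 9 (0.0625), over ranges of 0.00993 to 0.117, 0.0158 to 0.147, 0.0155 to 0.163 and 0.00634 to 0.163. Of the general stress genes 16 of 31 were lower with La, 27 adjusted over the list alone (adjusted p = 2.04e-15 and adjusted p = 0.298 with an estimated correlation). Of the pheromone response genes 6 of 14 were lower, 9 adjusted over the list alone (adjusted p = 2.19e-07 and adjusted p = 0.0492 with an estimated correlation). PRM1 changed by -1.32 ± 0.23 and PRM4 by -0.99 ± 0.09. Of the calcineurin targets 8 of 14 were lower, 10 adjusted over the list alone (adjusted p = 7.88e-14 and adjusted p = 0.0626 with an estimated correlation). In all 328 genes were called, 95 higher and 233 lower with La, 4 and 64 at least 2-fold.

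Averaged over both levels, RGI2 (-4.98 ± 0.39), YPT53 (-3.65 ± 0.24), HSP12 (-3.63 ± 0.25), CPP3 (-3.61 ± 0.20) and HXT5 (-3.60 ± 0.27) were lower with La (log2 ± SE; adjusted p up to 1.93e-07). The average difference was called in 1107 genes, 457 higher and 650 lower with La, 3 and 92 at least 2-fold. The 3 higher genes, named after their values were seen, were CSN9 (1.05 ± 0.27), the reductase gene FRE5 (1.03 ± 0.29) and YOR387C (1.04 ± 0.26). The step from EC10 to EC50 differed between the metals in 181 genes, 112 with a higher step for La. PHO89 had a step of 1.16 ± 0.09 with La and 0.07 ± 0.09 with Yb, a difference of 1.10 ± 0.12 (adjusted p = 0.00106), and HSP26 had -1.85 ± 0.35 and 0.46 ± 0.35, a difference of -2.31 ± 0.50 (adjusted p = 0.0323). That count moved with single libraries: it was 34 and 17 without Yb EC50 library 4 or 6, 481, 48 and 33 without Yb EC10 library 7, 8 or 9, 78 and 16 without La EC50 library 11 or 12, and 78, 80 and 46 without La EC10 library 13, 14 or 15. The call of HSP26 ended without La EC10 library 13 (0.06), La EC10 library 15 (0.0609), La EC50 library 12 (0.0924), Yb EC10 library 8 (0.0522), Yb EC50 library 4 (0.0774) or Yb EC50 library 6 (0.0619), over a range of 0.00435 to 0.0924.

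Many calls against control were shared. La EC50 and Yb EC50 had 493 genes higher in both and 513 lower in both, with 12 in opposite directions, where independent lists would share 145 and 146; La EC10 and Yb EC10 had 404 and 409, against 86.6 and 78.9. The doses shared 404 and 404 for La (71.9 and 72.9 for independent lists) and 748 and 613 for Yb (175 and 158). All 4 pairs share the 3 control libraries, and 100 simulations with unchanged groups gave at most 64 shared calls. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.82 for the doses of La, 0.88 for those of Yb, 0.67 for the metals at EC10 and 0.55 at EC50, where the simulations gave means of 0.51, 0.48, 0.54 and 0.46 and maxima of 0.88, 0.88, 0.89 and 0.83. The covariances were 0.0887, 0.174, 0.0823 and 0.0952, and exceeded the simulated means by 0.0789, 0.165, 0.0718 and 0.0862. With 3 controls no split keeps a pair of libraries on each side, so part of the excess of shared calls may come from the shared controls.

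**Figure D3:**
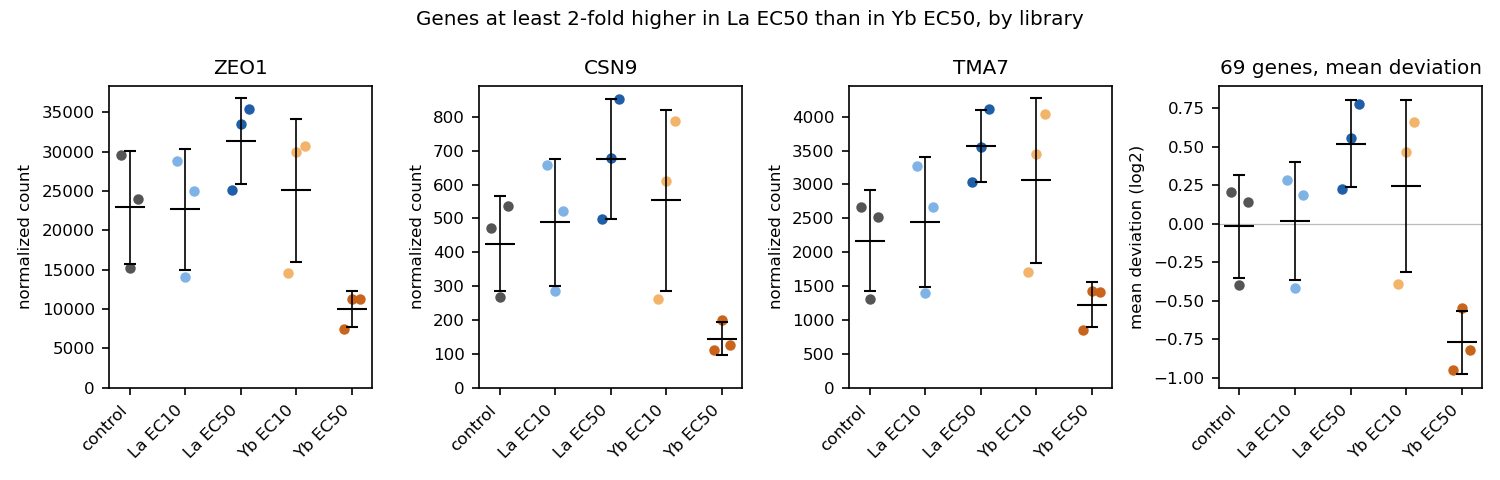
Normalized counts of ZEO1, CSN9 and TMA7, and the mean deviation (log2) of the 69 genes at least 2-fold higher in La EC50 than in Yb EC50, by library. Points are libraries, bars the mean and SD of 3 libraries per group. Control library 2, La EC10 library 14 and Yb EC10 library 7 lie below the other libraries of their groups for ZEO1, at 15239, 14091 and 14577.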

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

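The test of a component shared by libraries of a group, both tests of the general stress pattern, both tests of the mating pattern and the fit with the component removed were chosen only after the results were seen. A difference between the metals in the step from EC10 to EC50 flagged the values of the next paragraphs.

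The step from EC10 to EC50 differed between La and Yb in 181 genes. Of the named genes with a higher step for La, the difference in log2 was 2.34 for CSN9, 2.05 for YDL085C-A, 1.89 for TMA7, 1.88 for EFG1, 1.85 for EMC6, 1.83 for POP5, 1.79 for ZEO1, 1.79 for CNL1, 1.77 for TPM2, 1.71 for EXP1, 1.70 for MPC3, 1.66 for GIM4, 1.65 for DAD2, 1.59 for CGR1, 1.55 for URM1, 1.43 for PHO11, 1.10 for PHO89 and 0.99 for PHO12. With a lower step for La it was -0.66 for SHM2, -0.76 for ADE17, -0.77 for INO1, -1.72 for SPS19, -1.75 for FMP16, -1.78 for AQR1, -1.84 for TDH1 and -2.31 for HSP26. The adjusted p of these differences was 0.00106 for PHO89 and at most 0.0497, for TMA7. In the fit without the short-gene component 114 genes were called, and of these 26 genes EXP1, PHO11, PHO89, PHO12, SHM2, ADE17, SPS19, AQR1 and HSP26 stayed called. For the other 17 the adjusted p was then 0.0543 (INO1) to 0.225 (TMA7). Among them the differences were 0.83 for CSN9 (adjusted p = 0.0678, range 0.00239 to 0.121), 0.76 for YDL085C-A (adjusted p = 0.059, range 0.00223 to 0.112), 0.56 for TMA7 (adjusted p = 0.225, range 0.00477 to 0.225), 0.52 for EFG1 (adjusted p = 0.127, range 0.00249 to 0.128), 0.57 for EMC6 (adjusted p = 0.131, range 0.00278 to 0.131), -1.27 for TDH1 (adjusted p = 0.114, range 0.00744 to 0.128) and -1.32 for FMP16 (adjusted p = 0.0953, range 0.00452 to 0.128). No control library was left out for this difference. Whichever of the 12 La and Yb libraries was left out, PHO11, PHO89, SHM2, ADE17, SPS19 and AQR1 stayed called. Single libraries ended the calls of the other 20 (adjusted p in brackets). For CSN9 these were La EC10 library 14 (0.0768), La EC10 library 15 (0.0609), La EC50 library 11 (0.0688), La EC50 library 12 (0.121), Yb EC10 library 8 (0.0978), Yb EC10 library 9 (0.0988), Yb EC50 library 4 (0.0934) and Yb EC50 library 6 (0.0907). For YDL085C-A these were La EC10 library 14 (0.071), La EC10 library 15 (0.0595), La EC50 library 11 (0.0688), La EC50 library 12 (0.112), Yb EC10 library 8 (0.0942), Yb EC10 library 9 (0.0939), Yb EC50 library 4 (0.0905) and Yb EC50 library 6 (0.0907). For TMA7 these were La EC10 library 13 (0.0526), La EC10 library 14 (0.0988), La EC10 library 15 (0.0694), La EC50 library 10 (0.0581), La EC50 library 11 (0.0841), La EC50 library 12 (0.132), Yb EC10 library 8 (0.116), Yb EC10 library 9 (0.12), Yb EC50 library 4 (0.118), Yb EC50 library 5 (0.0607) and Yb EC50 library 6 (0.0922). For EFG1 these were La EC10 library 13 (0.0603), La EC10 library 14 (0.0949), La EC10 library 15 (0.0609), La EC50 library 11 (0.0823), La EC50 library 12 (0.128), Yb EC10 library 8 (0.11), Yb EC10 library 9 (0.11), Yb EC50 library 4 (0.111) and Yb EC50 library 6 (0.102). For EMC6 these were La EC10 library 13 (0.0556), La EC10 library 14 (0.0926), La EC10 library 15 (0.0609), La EC50 library 11 (0.0817), La EC50 library 12 (0.128), Yb EC10 library 8 (0.106), Yb EC10 library 9 (0.109), Yb EC50 library 4 (0.109) and Yb EC50 library 6 (0.101). For TDH1 these were La EC10 library 13 (0.0843), La EC10 library 15 (0.0879), La EC50 library 10 (0.0707), La EC50 library 11 (0.0722), La EC50 library 12 (0.128), Yb EC10 library 8 (0.0844), Yb EC10 library 9 (0.0733), Yb EC50 library 4 (0.112) and Yb EC50 library 6 (0.1). For FMP16 these were La EC10 library 13 (0.0855), La EC10 library 15 (0.0919), La EC50 library 10 (0.06), La EC50 library 11 (0.0816), La EC50 library 12 (0.128), Yb EC10 library 8 (0.105), Yb EC10 library 9 (0.0755), Yb EC50 library 4 (0.115), Yb EC50 library 5 (0.0587) and Yb EC50 library 6 (0.0907). For HSP26 these were La EC10 library 13 (0.06), La EC10 library 15 (0.0609), La EC50 library 12 (0.0924), Yb EC10 library 8 (0.0522), Yb EC50 library 4 (0.0774) and Yb EC50 library 6 (0.0619). Of the calls of the remaining 12 genes, 4 ended without La EC10 library 13 (0.0526 to 0.0635), 9 ended without La EC10 library 14 (0.0593 to 0.0949), 10 ended without La EC10 library 15 (0.0566 to 0.0776), 8 ended without La EC50 library 11 (0.0622 to 0.0841), 12 ended without La EC50 library 12 (0.0616 to 0.128), 9 ended without Yb EC10 library 8 (0.0594 to 0.107), 11 ended without Yb EC10 library 9 (0.0521 to 0.11), 11 ended without Yb EC50 library 4 (0.0524 to 0.111), 3 ended without Yb EC50 library 5 (0.0535 to 0.057) and 11 ended without Yb EC50 library 6 (0.056 to 0.105).

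The lists whose steps differed were called at the preset correlation, and none with an estimated correlation. The median differences of the dose steps, La minus Yb, were -0.77 for the general stress genes (adjusted p = 7.05e-17, and adjusted p = 0.342 with an estimated correlation), -0.49 for the osmotic stress genes (adjusted p = 5.84e-05, and adjusted p = 0.342 with an estimated correlation), -0.36 for the heat shock genes (adjusted p = 3.56e-11, and adjusted p = 0.0593 with an estimated correlation), 0.34 for the phosphate starvation genes (adjusted p = 2.79e-08, and adjusted p = 0.178 with an estimated correlation). They were -0.25 for the citrate cycle genes (adjusted p = 0.000105, and adjusted p = 0.178 with an estimated correlation), -0.20 for the Pdr1/Pdr3 genes (adjusted p = 0.0164, and adjusted p = 0.564 with an estimated correlation), -0.17 for the glycolysis genes (adjusted p = 0.000688, and adjusted p = 0.605 with an estimated correlation), 0.14 for the fatty acid genes (adjusted p = 0.0078, and adjusted p = 0.702 with an estimated correlation). The smallest were -0.12 for the nitrogen genes (adjusted p = 0.0123, and adjusted p = 0.564 with an estimated correlation), -0.0866 for the ribosome biogenesis genes (adjusted p = 0.0298, and adjusted p = 0.937 with an estimated correlation) and 0.0677 for the ribosomal protein genes (adjusted p = 0.0078, and adjusted p = 0.937 with an estimated correlation).

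Short genes were lower in Yb EC50 than in La EC50: the 69 genes had a median coding length of 366 bases against 1245 over all genes tested, and 61 of the 62 with a known length were under 1000. Removing each library's trend with coding length left 77.4% of the calls (48 of 62, 95% interval 65.6 to 86.0). The interval treats the genes as independent, which they are not, and does not measure the spread between libraries. The share did not clear a bound of 75% set in advance by more than that interval. With the trend removed the median log2 change was 1.16 (median SE 0.26) where it had been 1.26, a measure chosen after the percentage was seen. The trend is thus argued against only as the whole cause. Removing a trend with GC content left 95.2%, against GC content as the cause. Thinning every library to 5629666 reads left 98.6%. Totals already overlapped, at 6220111 to 7183175 reads in La EC50 and 6372092 to 6895514 in Yb EC50. Thinning could therefore hardly have changed the calls, and nothing is concluded from it. On a component of the differences between libraries of the same group, found in the 9 libraries outside the EC50 groups, 97.1% of the 69 genes (67) had the same sign, against 46.4% of all genes. Of the first 2 components, the one that went more with coding length was taken (Spearman rho 0.26). Short genes therefore tend to share a sign on it by that choice, and other short genes were not compared. Without the component the median log2 change went from 1.25 to 0.41 and 5 genes stayed called at least 2-fold higher. That removal also takes out any difference between the groups along the component, so it cannot tell such a difference from variation between libraries. A difference between libraries that also arises within groups may account for much of the pattern, and an effect of Yb itself stays open as untested.

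General stress genes were higher in Yb EC50 than in La EC50. The lowest Yb EC50 library lay 1.45 log2 above the highest La EC50 library in the mean of the list, more than the largest range within a group, 0.848 in Yb EC10. With the trend of coding length removed 100% of the 31 calls stayed. All 31 members were already called between these same libraries, so a gap in the list mean followed from those calls. It is no separate support. The median log2 difference was 0.11 for genes under 500 bases and -0.04 for those over 2000. Such a trend was too small to make a gap of 1.45. Its removal could hardly have ended these calls, and nothing is concluded from the removal. A different response to the metals stays open as a hypothesis, and so does the difference in concentration, 160 against 8 µM, since each level was matched by effect.

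The a-type mating genes were lower after La. Cells of the other mating type would bring their α-factor transcripts, and MF(ALPHA)1 reached at most 6.37 normalized counts in the 6 La libraries, below its highest control value of 11.7. Of the other α-type markers SAG1 rose at La EC50 (0.36 ± 0.08, adjusted p = 0.00283), which that test leaves unexplained, and STE3 was not called (0.27 ± 0.13 at La EC10, adjusted p = 0.149, and -0.23 ± 0.13 at La EC50, adjusted p = 0.201). A share of cells without a-type expression would lower all 7 markers alike, and their changes at La EC50 around a common log2 change of -0.79 gave a heterogeneity statistic of 93.9, where 12.6 is the 95% limit. The limit takes the genes as independent. The value argues against such a share as the only cause, and a share beside other changes of these genes stays open. A response of these genes to La stays open as a hypothesis.

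Other splits of the same libraries were counted. For comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each, gave 1131 genes for La EC10 against control (highest other 6), 1425 for La EC50 against control (1), 1629 for Yb EC10 (0), 2274 for Yb EC50 (0), 99 between the doses of La (0), 61 between the doses of Yb (0), 328 between the metals at EC10 (0), and 1224 at EC50 (0). For the difference in dose steps 3 of 100 splits gave at least 181 genes, the real one included, and the highest other gave 512. Why another split gave more genes than the real one was not tested. For the average difference only the real split, 1 of 100, gave 1107 genes (highest other 565). For the difference among the 5 groups only the real one, 1 of 100, gave 2402 (highest other 376). A share of 1 of 100 is the smallest that this number of splits can give. It makes chance unlikely for these counts but does not exclude it. Such splits also cannot tell an effect of the metals from another difference between the groups.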

How the results depend on the processing

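The fits with edgeR and DESeq2, and those with a trend or component removed, were chosen after seeing the data. No paired analysis was possible because the column names carry no replicate number, so no block could be fitted. That alternative was not run. The middle library of each group in column order was the lowest of its group for the general stress list in 5 of 5 groups. For the zinc list and for the heat shock list it was the lowest in 4 of 5. This was seen only afterwards among 30 lists, and further lists may share the pattern. Whether column order carries a shared batch is not known. No result changed direction past the threshold. The median of the histone list at La EC50, -0.07, was 0.03 with equal totals and 0.01 with quantile normalization, and that of the citrate cycle list for La EC10 against Yb EC10, -0.04, was 0.02 with quantile normalization. Those lists were not called there. Outside the fits that leave out a library, named genes kept their call in 1366 values and lost it in 69. Lists kept it in 518 and lost it in 98, of which 80 came with an estimated correlation. Without single libraries these counts were 636 and 132 for named genes and 488 and 40 for lists. For the difference in dose steps, 181 became 70 with no filter on low values, 36 with limma without a trend and robust, 114 with the short-gene component removed, 273 with edgeR and 353 with DESeq2. For Yb EC50 against Yb EC10, 61 became 19 with no filter, 203 with equal totals, 142 with quantile normalization, 5 with limma without a trend, 0 with only the 6 libraries, 176 with edgeR and 309 with DESeq2. La EC10 against Yb EC10 went from 328 to 502 with the component removed and 142 with only the 6 libraries, and La EC50 against La EC10 from 99 to 230 with the component removed and 169 with DESeq2. The cause was not tested. With an estimated correlation the lists called went from 15 to 2 (La EC10 against control), 15 to 3 (La EC50), 17 to 1 (Yb EC10), 18 to 1 (Yb EC50), 13 to 1 (La EC10 against Yb EC10) and 10 to 0 (La EC50 against Yb EC50). Leaving out a library gave 577 to 1511 genes for La EC10 against control, 989 to 1424 for La EC50, 989 to 1818 for Yb EC10, 1515 to 2122 for Yb EC50, 32 to 100 between the doses of La, 0 to 536 between those of Yb, 220 to 359 and 789 to 1033 between the metals at EC10 and EC50, 16 to 481 for the dose steps, 867 to 1185 for the average and 1747 to 2658 among the 5 groups. Depth limits low genes, since 0 reads in a library allows up to 2.70 to 3.67 normalized counts.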

Other observations

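The hexose transporter gene HXT7 changed by 1.41 ± 0.30, 1.77 ± 0.30, 1.61 ± 0.30 and 2.16 ± 0.30 (log2 ± SE, n = 3) at La EC10, La EC50, Yb EC10 and Yb EC50, while the low-affinity transporter gene HXT1 changed by -0.66 ± 0.09 at La EC50. Of the hexose transport genes 7 of 13 rose and 2 fell, or 7 and 2 adjusted over the list alone at Yb EC50 (adjusted p = 0.0501 and adjusted p = 0.384 with an estimated correlation). Of the nitrogen catabolite repression genes 8 of 18 rose and 0 fell, or 11 and 0 adjusted over the list alone at Yb EC50 (adjusted p = 0.000946 and adjusted p = 0.211 with an estimated correlation). The amino acid permease gene GAP1 changed by 2.02 ± 0.20 there. The ammonium transporter gene MEP1 changed by -0.99 ± 0.16 at La EC50 and was -2.08 ± 0.16 apart in La EC50 against Yb EC50. Of the citrate and glyoxylate cycle genes 1 of 16 rose and 3 fell, or 1 and 3 adjusted over the list alone at La EC50 (adjusted p = 0.461 and adjusted p = 0.723 with an estimated correlation). The aconitase gene ACO1 changed by -0.75 ± 0.07 and the isocitrate dehydrogenase genes IDH1 and IDH2 by -0.64 ± 0.07 and -0.65 ± 0.06. At Yb EC50 7 of 16 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p = 0.00339 and adjusted p = 0.188 with an estimated correlation). LSC2 changed by 0.92 ± 0.08. Of the glycolysis genes 1 of 18 rose and 0 fell, or 1 and 0 adjusted over the list alone at Yb EC50 (adjusted p = 0.482 and adjusted p = 0.824 with an estimated correlation). The glucokinase gene GLK1 changed by 1.88 ± 0.17. At La EC50 the glycolysis list was called lower, with a median of -0.12 with equal totals (camera adjusted p = 0.0102). That call ended with quantile normalization (camera adjusted p = 0.912) and did not hold with an estimated correlation. Of the Gcn4 targets of amino acid synthesis 2 of 36 rose and 21 fell, or 2 and 21 adjusted over the list alone at Yb EC50 (adjusted p = 1.25e-05 and adjusted p = 0.305 with an estimated correlation). HIS4 changed by -0.95 ± 0.05 at La EC50. Of the sulfur amino acid genes 0 of 25 rose and 4 fell, or 0 and 4 adjusted over the list alone at La EC50 (adjusted p = 0.206 and adjusted p = 0.618 with an estimated correlation). The methionine synthase gene MET6 changed by -1.01 ± 0.09.

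Few genes of metal uptake were called. Of the zinc regulon 3 of 15 rose and 0 fell, or 6 and 1 adjusted over the list alone at La EC10 (median 0.45, adjusted p = 0.00538 and adjusted p = 0.607 with an estimated correlation). VEL1 changed by 1.72 ± 0.38 and ADH4 by 0.89 ± 0.27. The zinc list was also higher in La EC10 against Yb EC10 (median 0.58 with equal totals, camera adjusted p = 8.08e-08). There VEL1 and ADH4 lost their calls without single La EC10 or Yb EC10 libraries. In La EC50 against Yb EC50 the zinc list's median was 0.27 with equal totals (camera adjusted p = 0.00994). Neither call held with an estimated correlation. Of the iron regulon 2 of 23 rose and 0 fell, or 1 and 0 adjusted over the list alone at La EC10 (median 0.26, adjusted p = 0.019 and adjusted p = 0.777 with an estimated correlation), and that call ended without control library 2 (0.076), La EC10 library 13 (0.0722) or La EC10 library 15 (0.176), with equal totals (0.0585) and with the short-gene component removed (0.0582), over a range of 0.000289 to 0.176. Its mean deviation was -0.0488 in La EC10 library 14, within the control range of -0.122 to 0.128, and 0.436 and 0.531 in libraries 13 and 15. In La EC10 against Yb EC10 the list was higher (median 0.32, adjusted p = 1.46e-05 and adjusted p = 0.578 with an estimated correlation), with 1 gene called, or 7 adjusted over the list alone. There La EC10 library 14 lay below Yb EC10 libraries 7 and 9 (0.119 and 0.104), and Yb EC10 library 8 was at -0.474. In La EC50 against Yb EC50 it was higher by a median of 0.16 (adjusted p = 0.0378 and adjusted p = 0.924 with an estimated correlation), with 2 genes called, or 0 adjusted over the list alone, and that call ended without La EC50 library 11 (0.18), Yb EC50 library 5 (0.218) or Yb EC50 library 6 (0.0701), over a range of 0.000247 to 0.218. The mean deviations of the libraries overlapped, with -0.0773, 0.162 and -0.0394 for La EC50 and -0.021, -0.439 and -0.236 for Yb EC50. At Yb EC50 0 of 23 rose and 3 fell, or 0 and 2 adjusted over the list alone and the list was not called (adjusted p = 0.0962 and adjusted p = 0.705 with an estimated correlation). The iron permease gene FTR1 changed by -0.77 ± 0.13 and the oxidase gene FET3 by -0.71 ± 0.17. Of the copper genes 1 of 8 rose and 0 fell, or 1 and 0 adjusted over the list alone (adjusted p = 0.852 and adjusted p = 0.864 with an estimated correlation). CUP2 changed by 0.55 ± 0.14. Of the oxidative stress genes 3 of 21 rose and 2 fell, or 3 and 2 adjusted over the list alone at Yb EC50 (adjusted p = 0.931 and adjusted p = 0.936 with an estimated correlation). The peroxidase gene GPX2 changed by -0.66 ± 0.17. Of the ergosterol genes 1 of 24 rose and 7 fell, or 2 and 8 adjusted over the list alone at La EC10 (adjusted p = 0.00196 and adjusted p = 0.0525 with an estimated correlation). ERG3 changed by -0.53 ± 0.07. Of the fatty acid and sphingolipid genes 9 of 25 rose and 8 fell, or 10 and 9 adjusted over the list alone at Yb EC50 (adjusted p = 0.482 and adjusted p = 0.824 with an estimated correlation). SUR1 changed by 1.04 ± 0.08. At La EC50 the fatty acid and sphingolipid list was called higher. Its median there was 0.24 with equal totals (camera adjusted p = 0.0143) and 0.14 with quantile normalization (camera adjusted p = 0.00153). That call did not hold with an estimated correlation.

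Of the Rim101 and ESCRT genes 11 of 23 rose and 1 fell, or 11 and 1 adjusted over the list alone at Yb EC50 (adjusted p = 0.00706 and adjusted p = 0.211 with an estimated correlation). VPS36 changed by 0.78 ± 0.09. Of the vacuolar H+-ATPase genes 1 of 15 rose and 1 fell, or 1 and 0 adjusted over the list alone (adjusted p = 0.56 and adjusted p = 0.638 with an estimated correlation). STV1 changed by 0.25 ± 0.07. Of the histone genes 0 of 10 rose and 8 fell, or 0 and 8 adjusted over the list alone (adjusted p = 0.000282 and adjusted p = 0.229 with an estimated correlation). HHF1 changed by -0.49 ± 0.09; with quantile normalization the list's adjusted p was 0.0573, over a range of 8.17e-06 to 0.0573. Of the cell cycle genes 1 of 19 rose and 10 fell, or 1 and 10 adjusted over the list alone (adjusted p = 0.00592 and adjusted p = 0.136 with an estimated correlation). The cyclin gene CLB6 changed by -0.54 ± 0.16. Of the proteasome genes 5 of 33 rose and 0 fell, or 0 and 0 adjusted over the list alone (adjusted p = 0.0325 and adjusted p = 0.392 with an estimated correlation). RPT3 changed by 0.24 ± 0.07, and that list's call ended without control library 1 (0.0548), control library 2 (0.0573) or Yb EC50 library 5 (0.0657), over a range of 0.00067 to 0.0657.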
